A study of Homo sapiens with 6 samples.

How the data were processed

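Poly(A) RNA was sequenced from HEK-293 cells, a human embryonic kidney line, that had been transfected with equal amounts (1.25 µg each) of a plasmid for the hERG potassium channel and a plasmid for hERG carrying the A561V change. The cells then received 15 µM lumacaftor or the solvent DMSO for 24 h, with 3 libraries per group. Libraries were strand-specific, per the labels' protocols. Trimmomatic 0.36, HISAT2 2.1.0, featureCounts 1.6.2, DESeq2 1.22.2 and the hg38 build are named in the submitters' processing notes, which give no role or order for them. The annotation release and the counting settings are not given in the sources used here.

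The deposited table lists 17623 genes by Entrez gene ID and symbol. Its expected counts, as deposited by the authors, were not normalized, and 8.38% of the values were not whole numbers, for which the sources used here give no reason. The design had assumed whole counts. The expected counts were therefore rounded to whole numbers before any count test. The deposited TPM values, which are scaled for transcript length and library, were made by the authors and summed to 999999 to 1000000 per library over the table. Of 10200 genes with a mean count of at least 200, the ratio of TPM to count, after scaling between libraries, varied by over 1% for 60.1% and by over 10% for 8.46%, so TPM did not divide the counts by 1 fixed length per gene. The 12 other columns of values, 6 of FPKM and 6 of the authors' group averages, were not used.

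Library totals ran from 14471014 to 16222888 counts. Genes were kept by the filterByExpr defaults of edgeR (minimum count 10, minimum total count 15), which left 13997 genes. Counts were scaled with TMM factors, and the groups were compared with edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with group as the only term. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes are the fitted log2 ratios of lumacaftor over DMSO, and each SE was derived from the F statistic. CPM is a count over its TMM-scaled library total, times 1000000. Values after ± are SDs over 3 libraries unless SE is named. The labels give no word on whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Among pairs of libraries within a group, the chi-square per degree of freedom of the counts was at least 3.74, so no library repeated another. The interval given for a share of counts is a 95% Wilson interval and covers counting error only.

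The 28 gene lists held 820 entries, of which 794 matched the table through symbols or Entrez IDs. The 27 lists with at least 5 tested members were tested with camera, two-sided, with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was run again with the correlation estimated from the data, and the rotation test fry was run in its directional and mixed forms. The mitochondrially encoded transcripts were not analysed here, since none of the 13 listed symbols matched the table. The genes named were fixed by rule. They were KCNH2, then the 10 higher and 10 lower genes with the largest fitted fold among those past the threshold, with an average log2 CPM of at least 1 and no overlap between the groups' libraries. From each list they were the 3 members with the lowest adjusted p past the threshold, or, where none passed, the 2 with the highest mean CPM. FKBP8, EBP, SMAD7, TGFB1, ALDOC, PGK1 and TALDO1 are further members of such lists and were named after their values were seen. A gene that the rule selects and some list members that passed the threshold are left out of the text. Lists, tests, the rule for named genes and the alternatives listed first below were set before the data were examined.

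Gene positions are those of RefSeq on GRCh38, the assembly that hg38 denotes, matched by Entrez ID for 17491 of the 17623 genes. GC content and length came from GENCODE 29 transcripts and were available for 99.0% of the tested genes. Alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 50 counts in at least 3 libraries, the replicate number as a block, 6 fits that each left out 1 library, an adjusted p threshold of 0.01, glmTreat against a fold of 1.2, and limma-trend on log2(TPM + 1) or log2(TPM + 0.1). Those chosen after seeing the data were log2 KCNH2 as a covariate, a per-library loess correction on GC content (span 0.5), the pair together, KCNH2 left out of the table, and camera with an estimated correlation in the fits with 1 library left out and in those with the covariate.

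The main fit was tested on simulated counts for the comparison of lumacaftor with DMSO over the 13997 genes. It recovered 79% of 100 genes changed 1.5-fold and 95% of 100 genes changed 2-fold, with 14 false calls. A simulated trend of -0.3 log2 per 10% GC with no changed gene gave 4888 calls without the GC correction and 3 with it, and the corrected fit recovered 94% of genes changed 2-fold. That trend was the same in each lumacaftor library and steeper than in the data. There the median log2 fold change ran from 0.08 in the lowest decile of GC content to -0.12 in the highest. The 4888 calls are therefore no estimate of false calls in the data. In simulated data with 1 list moved by 0.3 log2, camera called that list and 0 of the other 26. The simulated genes were independent of each other, so camera was not tested on lists whose members move together.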

Results

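The data comprised 6 RNA-seq libraries from HEK-293 cells expressing the hERG channel together with its A561V form, 3 treated with lumacaftor (15 µM, 24 h) and 3 with DMSO. Lumacaftor is a small-molecule corrector developed for misfolded CFTR, and hERG is the cardiac potassium channel encoded by KCNH2. The comparison addressed which transcripts differ in these cells with and without the compound. Totals were 14471014, 16016452 and 16222888 counts in DMSO libraries 1, 2 and 3, and 15514988, 16190110 and 15754291 in lumacaftor libraries 1, 2 and 3. Of 17623 genes listed, 13997 were tested.

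KCNH2 (Entrez 3757, hg38 chromosome 7, 150944961 to 150978321) was abundant in every library, and its levels overlapped between the groups. It stood at 6046, 5061 and 15408 CPM in DMSO libraries 1, 2 and 3 and at 10881, 16817 and 11265 CPM in lumacaftor libraries 1, 2 and 3. Its share of all counts ran from 0.51% (95% Wilson interval 0.507 to 0.514) in DMSO library 2 to 1.68% (1.68 to 1.69) in lumacaftor library 2. The group means were 8838 ± 5710 CPM (SD, n = 3) with DMSO and 12988 ± 3322 CPM (SD, n = 3) with lumacaftor. The log2 fold change of 0.56 ± 0.33 (SE) was within the spread between libraries (adjusted p = 0.339). Without DMSO library 3 the log2 fold change was 1.23 ± 0.14 (SE, adjusted p = 5.95e-05). Gene counts do not separate the plasmid alleles from each other or from the endogenous gene.

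Interferon response genes differed between libraries of a group more than between the groups. None of the 32 tested members passed the edgeR test, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (camera adjusted p = 0.529). IFIT1, an antiviral RNA-binding protein, stood at 711, 555 and 1894 CPM in DMSO libraries 1, 2 and 3 and at 891, 1152 and 668 CPM in lumacaftor libraries 1, 2 and 3 (log2 fold change -0.22 ± 0.36 SE, adjusted p = 0.751). DMSO library 3 also stood apart from the other DMSO libraries on the second principal component (29.7% of the variance), at -20.97 against 13.69 and 16.44 for DMSO libraries 1 and 2. Lumacaftor library 2 lay on the same side at -11.0, and lumacaftor libraries 1 and 3 at -0.10 and 1.95. Without DMSO library 3 the list lay higher after lumacaftor (camera adjusted p = 1.29e-12) and IFIT1 had a log2 fold change of 0.51 (adjusted p = 0.0369). Without DMSO library 1, DMSO library 2 or lumacaftor library 2 the list lay lower, with camera adjusted p = 0.0159, 0.00165 and 0.0329. These calls rest on the preset correlation, since the members move together. With an estimated correlation the adjusted p was 0.933 over all libraries, 0.633 without DMSO library 3, and 0.779, 0.7 and 0.806 without DMSO library 1, DMSO library 2 and lumacaftor library 2.

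**Figure D1:**
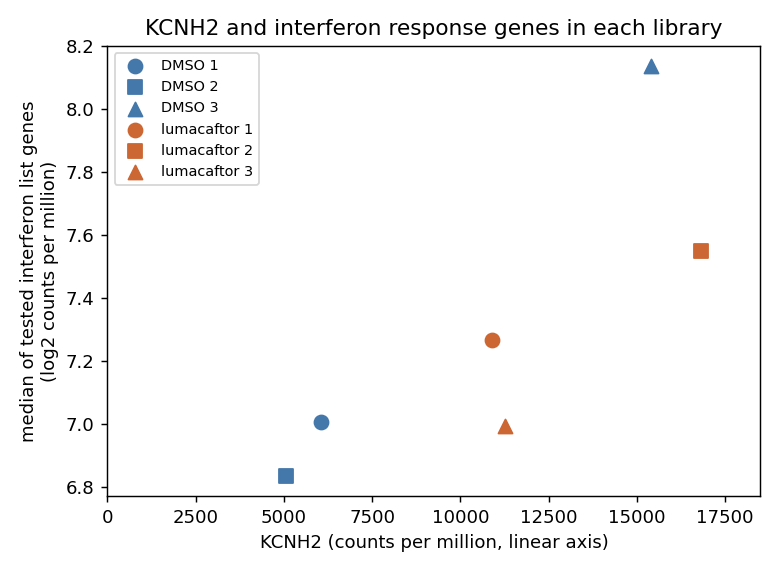
KCNH2 in CPM (x axis, linear) against the median log2 CPM of the 32 tested interferon list genes (y axis), 1 point per library, blue for DMSO and orange for lumacaftor. DMSO library 3 lies highest on the y axis at 8.14, with 15408 CPM of KCNH2, while DMSO libraries 1 and 2 lie at 7.01 and 6.84.

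On counts, lumacaftor was followed by more decreases than increases. After treatment 246 genes were higher and 574 lower (edgeR, adjusted p under 0.05), and 10 of the higher and 30 of the lower genes reached a fitted 2-fold change. With limma-trend, 212 genes were higher and 218 lower on log2(TPM + 1), and 215 higher and 213 lower on log2(TPM + 0.1), so the excess of decreases on counts was not matched on TPM. The TPM fits had no TMM scaling. Their median log2 fold change over all tested genes was 0.06 and 0.07, against 0.003 in the main fit, so part of the difference may be one of scaling. The median absolute log2 fold change of the 820 genes was 0.39. Among the decreases, BMPER, a secreted regulator of bone morphogenetic proteins (chromosome 7, 33904915 to 34156427), fell from 5.51 ± 0.968 to 1.6 ± 0.113 CPM (SD, n = 3 each, log2 fold change -1.78 ± 0.20 SE, adjusted p = 0.00264). CGA, the common alpha subunit of the glycoprotein hormones (chromosome 6, 87085498 to 87095106), fell from 16.2 ± 1.53 to 4.95 ± 1.52 CPM (-1.71 ± 0.19 SE, adjusted p = 0.00264). ETV4, an ETS-family transcription factor (chromosome 17, 43527846 to 43546340), fell from 10.3 ± 1.3 to 3.35 ± 0.798 CPM (-1.62 ± 0.18 SE, adjusted p = 0.00264). DACT2, a Dishevelled-binding protein, fell from 5.32 ± 0.488 to 1.78 ± 0.261 CPM (-1.57 ± 0.19 SE, adjusted p = 0.00286). ITGA8 (integrin alpha 8), NCKAP5, LRRTM1, RFX6 (a transcription factor of pancreatic endocrine cells), GIPC3 and SFRP2 (a secreted Frizzled-related protein) fell with log2 fold changes of -1.32, -1.2, -1.19, -1.17, -1.12 and -1.09 and adjusted p between 0.00549 for GIPC3 and 0.0373 for NCKAP5. NCKAP5 stood at 11.7 CPM in DMSO library 3 against 4.88 and 6.32 CPM in DMSO libraries 1 and 2, and without DMSO library 3 its log2 fold change was -0.75 (adjusted p = 0.0218). It missed the threshold without lumacaftor library 1, 2 or 3 (adjusted p = 0.146, 0.0847 and 0.113). The counts of changed genes depended on single libraries. Leaving out 1 library, and so testing fewer samples, gave 16 higher and 118 lower genes without DMSO library 1, 20 and 110 without lumacaftor library 1, 24 and 138 without lumacaftor library 2, 63 and 228 without lumacaftor library 3, 195 and 443 without DMSO library 2, and 468 and 880 without DMSO library 3. BMPER, CGA, ETV4, DACT2, GIPC3, DHRS2, SLC7A11, HSPA1B, CAV1 and SREBF1 were the 10 of 63 named changed genes that passed the threshold in each of the 6 fits with 1 library left out.

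Among the increases, DHRS2, a short-chain dehydrogenase/reductase (chromosome 14, 23630115 to 23645639), rose from 11.1 ± 2.85 to 25.5 ± 5.06 CPM (SD, n = 3 each, log2 fold change 1.2 ± 0.18 SE, adjusted p = 0.00575). SLC7A11, the cystine/glutamate exchanger (chromosome 4, 138164097 to 138242349), rose from 16.8 ± 1.24 to 27.9 ± 3.45 CPM (0.74 ± 0.10 SE, adjusted p = 0.00458). DNAH3 (an axonemal dynein heavy chain), SLC16A6 (a monocarboxylate transporter family member), CRISPLD2, CHGA (chromogranin A, a secretory granule protein) and IQCN rose with log2 fold changes of 1.19, 1.12, 1.04, 0.92 and 0.81 from DMSO means between 1.32 and 3.05 CPM. LOC112268238, an uncharacterised locus, rose from 11.4 ± 2.92 to 20.9 ± 2.25 CPM (0.87 ± 0.16 SE, adjusted p = 0.0124). RBM14-RBM4 (1.15) is a readthrough locus that shares exons with RBM14 and RBM4, and ZNF737 (0.88) belongs to a cluster of similar zinc finger genes, so both values are uncertain.

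**Figure D2:**
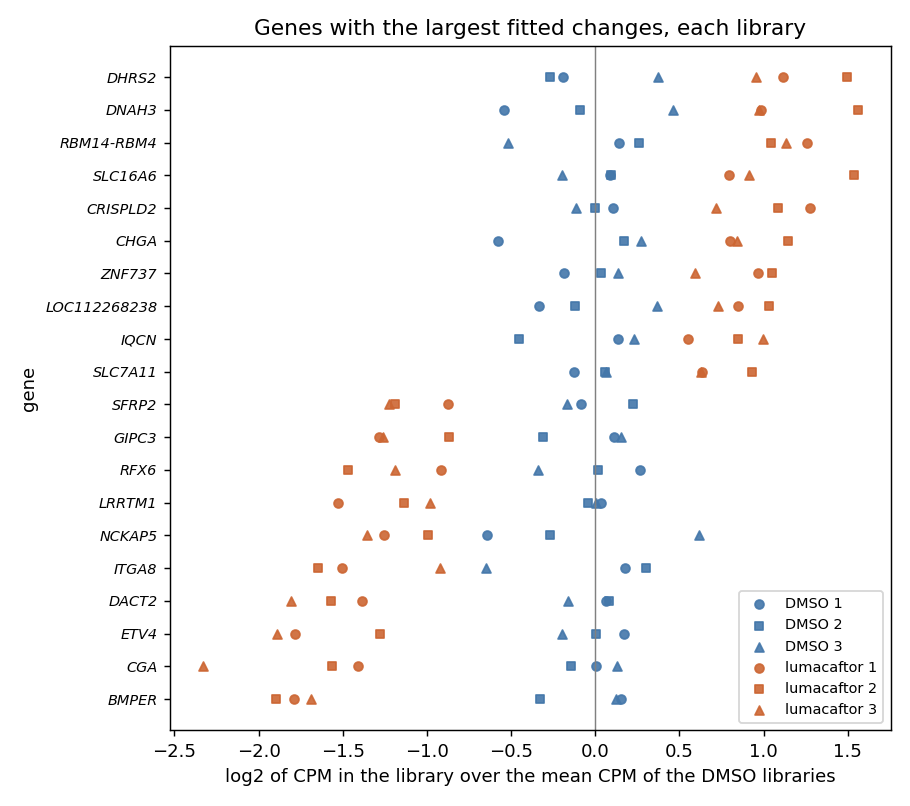
The 20 named genes with the largest fitted changes (y axis) and, for each of the 6 libraries, the log2 ratio of its CPM to the mean CPM of the DMSO libraries (x axis), blue for DMSO and orange for lumacaftor. For each gene the 3 lumacaftor libraries lie on 1 side of the 3 DMSO libraries, as the rule for naming them required.

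Few genes for folding and degradation of membrane proteins in the endoplasmic reticulum passed the threshold, but so did only 5.86% of all tested genes. Of 26 ER chaperone genes 7 had an unadjusted p under 0.05, against 3391 of 13997 tested genes. Mixed fry, which counts changes in either direction, called the ER chaperone and ER-associated degradation lists (adjusted p = 0.00105 and 0.000246), among 23 of 27 lists. These genes were thus not shown to change less than others. Of 26 tested ER chaperone and unfolded protein response genes, 1 rose, SIL1, a nucleotide exchange factor for the chaperone BiP, from 25.7 ± 1.06 to 31.2 ± 0.88 CPM (adjusted p = 0.0402), and 3 were higher adjusted over the list alone (camera adjusted p = 0.865). Of 25 ER-associated degradation genes, 1 fell, DERL3 (a derlin), from 25.5 ± 2.21 to 18 ± 0.917 CPM (adjusted p = 0.0119), as did 1 adjusted over the list alone, although 21 of the 25 fitted folds were positive (median 0.08, camera adjusted p = 0.11). That list passed as higher with limma-voom (camera adjusted p = 0.0389), on log2(TPM + 1) (0.0251) and without DMSO library 1 (0.0407), but with an estimated correlation the adjusted p was 0.607 over all libraries and 0.676 without DMSO library 1. SLC7A11 was the 1 member of 33 integrated stress response genes to rise, and 1 was higher adjusted over the list alone (camera adjusted p = 0.865). Among 41 COPII and early secretory genes, 0 passed the edgeR test and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom (camera adjusted p = 0.155, and 0.041 on log2(TPM + 1), but on counts with an estimated correlation adjusted p = 0.7). ARF1, a GTPase of the COPI coat, averaged 635 ± 10.9 CPM with DMSO and 636 ± 16.8 CPM with lumacaftor, and SURF4, a cargo receptor, 418 ± 25.4 and 413 ± 5.38 CPM. Of 36 N-glycosylation genes, 2 rose, and 2 were higher adjusted over the list alone (camera adjusted p = 0.482). These were MAGT1, an oligosaccharyltransferase subunit, with a log2 fold change of 0.29 ± 0.06 (SE), and FUT8, the core fucosyltransferase, with 0.32 ± 0.08.

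Cytosolic heat-shock genes moved both ways. Of 26 tested, 2 rose and 2 fell, against 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.883). HSPA1B and HSPA1A, which encode the inducible HSP70, rose from 735 ± 42.7 to 1005 ± 72.8 CPM (adjusted p = 0.00588) and from 788 ± 84.4 to 1042 ± 51 CPM (adjusted p = 0.0152). These near-identical copies can share reads, so the division between them is uncertain. HSPB1 (HSP27) fell from 123 ± 7.57 to 87.3 ± 10.7 CPM (adjusted p = 0.0113), and HSPE1 (HSP10), a gene with processed pseudogenes, from 84.9 ± 3.97 to 68.2 ± 1.19 CPM (adjusted p = 0.0134). Among 28 tested folding and trafficking partners of hERG, a list that includes KCNH2, HSPA1A rose and 3 genes fell, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.432). The 3 were CAV1 (caveolin 1, 74.2 ± 1.76 to 55.4 ± 3.37 CPM, adjusted p = 0.00606), TRIOBP (116 ± 5.19 to 96.4 ± 4.37 CPM, adjusted p = 0.0271) and FKBP8, a co-chaperone (log2 fold change -0.26, adjusted p = 0.0356).

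Some genes of the cholesterol list fell, but neither it nor the fatty acid and lipid list passed the camera test with all libraries. On log2(TPM + 1), limma-trend called 0 members of the cholesterol list, and its camera adjusted p was 0.258. Of 25 tested cholesterol synthesis genes and SREBP2 targets, 5 fell, and 5 were lower adjusted over the list alone (camera adjusted p = 0.11, and 0.0159 without DMSO library 1, but with an estimated correlation adjusted p = 0.7 and 0.676). Among them were ACAT2 and FDPS, enzymes of the pathway, with log2 fold changes of -0.31 and -0.26, INSIG1, which retains SREBP in the ER, with -0.28, and the sterol isomerase EBP with -0.23. Of 24 fatty acid and lipid genes, 2 fell and 1 rose, with 5 lower and 1 higher adjusted over the list alone, and 14 of the 24 fitted folds were positive (camera adjusted p = 0.883). SREBF1, the gene of the lipogenic transcription factor SREBP1, fell from 74.6 ± 0.295 to 53.9 ± 3 CPM (SD, n = 3, log2 fold change -0.47 ± 0.06 SE, adjusted p = 0.00402), FADS2, a fatty acid desaturase, had a log2 fold change of -0.23 ± 0.06, and CPT2, of mitochondrial fatty acid import, 0.23 ± 0.06. Of 12 xenobiotic metabolism and drug transport genes, 2 fell, against 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.722). These were the efflux transporter ABCG2 (5.72 ± 0.563 to 3.61 ± 0.297 CPM) and CYP1B1 (44.6 ± 3.7 to 35.8 ± 2.3 CPM).

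Of 25 tested NRF2 oxidative stress targets, 3 rose and 1 fell, against 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.281). Besides SLC7A11, the glutathione synthesis enzyme GCLC rose from 75.2 ± 2.78 to 91.3 ± 4.5 CPM (adjusted p = 0.0231) and heme oxygenase HMOX1 from 70.8 ± 25 to 118 ± 17.8 CPM (adjusted p = 0.0462). HMOX1 stood at 99.6 CPM in DMSO library 3 and at 54.6 and 58.2 CPM in DMSO libraries 1 and 2. TALDO1, of the pentose phosphate pathway, fell (log2 fold change -0.21, adjusted p = 0.0484). In the proteasome list 1 of 31 fell (PSMB6, log2 fold change -0.22) and 0 passed adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 1 called by DESeq2 and 1 by limma-voom (camera adjusted p = 0.112). The proteasome list passed as lower with DESeq2 (camera adjusted p = 0.0464) and limma-voom (0.0389), and without lumacaftor library 1 (0.0276), but with an estimated correlation the adjusted p was 0.721 over all libraries and 0.68 without lumacaftor library 1. In the autophagy and lysosome list 1 of 32 rose (WIPI1, 0.33) and 0 passed adjusted over the list alone, with 8 at an unadjusted p under 0.05, 1 called by DESeq2 and 2 by limma-voom (camera adjusted p = 0.723).

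Genes of glycolysis and hypoxia were higher as a list. Of 32 tested members 5 rose, and 9 were higher adjusted over the list alone (camera adjusted p = 0.0133, but adjusted p = 0.607 with an estimated correlation). NDRG1, a hypoxia-induced gene, rose from 55.5 ± 4.21 to 74.1 ± 8.81 CPM (adjusted p = 0.0237), and BNIP3 and BNIP3L, mitophagy receptors, had log2 fold changes of 0.29 and 0.38. ALDOC and PGK1, glycolytic enzymes, had 0.62 and 0.28. Without lumacaftor library 2 the list had camera adjusted p = 0.084. Nuclear genes of oxidative phosphorylation were lower as a list, with 33 of 41 fitted folds negative and a median of -0.08 (camera adjusted p = 0.0289, but adjusted p = 0.607 with an estimated correlation). The 1 member that fell was NDUFB10, of complex I (195 ± 9.88 to 151 ± 10.5 CPM, adjusted p = 0.0124), as did 1 adjusted over the list alone. Without DMSO library 1, lumacaftor library 2 or lumacaftor library 3 the oxidative phosphorylation list had camera adjusted p = 0.0865, 0.084 and 0.0556, and 0.131 on log2(TPM + 1). Cytosolic ribosomal protein genes were lower, with 46 of 47 fitted folds negative and a median of -0.15 (camera adjusted p = 9.04e-06, but adjusted p = 0.607 with an estimated correlation). Of these 4 fell, among them RPL27, RPL38 and RPL11 (log2 fold changes -0.28, -0.48 and -0.27), and 6 were lower adjusted over the list alone. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain.

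Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were higher as a list at low levels. All 14 tested members had positive fitted folds (median 0.49, camera adjusted p = 0.000138, but adjusted p = 0.607 with an estimated correlation). H2AC8 alone rose, from 0.772 ± 0.0938 to 1.66 ± 0.344 CPM (adjusted p = 0.0466), and 4 were higher adjusted over the list alone. These genes are close paralogs, and their counts are uncertain. Of 25 p53 targets 3 rose, and 5 were higher adjusted over the list alone (camera adjusted p = 0.0321, but adjusted p = 0.607 with an estimated correlation). MDM2, the ubiquitin ligase of p53, rose from 146 ± 7.15 to 179 ± 6.92 CPM (adjusted p = 0.0168), SESN1 from 45.7 ± 3.55 to 55.9 ± 0.764 CPM (adjusted p = 0.0389) and the DNA repair gene XPC from 63.4 ± 3.39 to 75.6 ± 3.86 CPM (adjusted p = 0.0439). Without DMSO library 1 or lumacaftor library 2 the p53 list had camera adjusted p = 0.123 and 0.128. RRM2, a ribonucleotide reductase subunit, was the 1 of 30 DNA replication genes to rise (333 ± 13.7 to 405 ± 5.68 CPM, adjusted p = 0.018), as did 1 adjusted over the list alone (camera adjusted p = 0.434). Among 30 mitosis genes 0 passed the edgeR test and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.511). The proliferation marker MKI67 averaged 1065 ± 78 CPM with DMSO and 1106 ± 88.2 CPM with lumacaftor, and TOP2A 665 ± 59.2 and 725 ± 19.9 CPM.

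Of 40 tested ion channel genes 1 fell, the T-type calcium channel CACNA1G (17.8 ± 1.29 to 13.1 ± 1.2 CPM, adjusted p = 0.0329), as did 1 adjusted over the list alone (camera adjusted p = 0.11, and 0.0251 on log2(TPM + 1), but on counts with an estimated correlation adjusted p = 0.607). Of 29 extracellular matrix and TGF-beta genes 5 fell, against 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0524). The list passed as lower with DESeq2 (camera adjusted p = 0.0194) and limma-voom (0.0389), and without DMSO library 1 (0.0444), DMSO library 3 (0.0311) or lumacaftor library 2 (0.0179), but with an estimated correlation the adjusted p was 0.607 over all libraries and 0.676, 0.633 and 0.635 without these in turn. The 5 genes were the laminin chain LAMB1 (98.9 ± 8.32 to 75.5 ± 2.67 CPM), the collagen COL6A1 (301 ± 0.532 to 241 ± 19.5 CPM), the protease inhibitor TIMP1 (137 ± 6.51 to 114 ± 5.16 CPM), SMAD7 (log2 fold change -0.32) and TGFB1 (-0.24). DUSP6, a phosphatase of ERK, was the 1 of 25 NF-kappaB targets and immediate early genes to fall (7.2 ± 1.89 to 3.9 ± 0.333 CPM, adjusted p = 0.0292), as did 1 adjusted over the list alone (camera adjusted p = 0.434, and 0.0409 without DMSO library 2, but with an estimated correlation adjusted p = 0.933 and 0.682).

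Markers of other cell types were few and partly belong to HEK-293 itself. Of 6 tested fibroblast and endothelial markers 2 fell, KDR (4.88 ± 0.703 to 2.54 ± 0.409 CPM) and VIM (1803 ± 98 to 1523 ± 89.2 CPM), and 4 were lower adjusted over the list alone (camera adjusted p = 0.0289, but adjusted p = 0.607 with an estimated correlation). Of 6 hepatocyte and squamous markers 2 fell, KRT18 (243 ± 27.7 to 190 ± 8.27 CPM) and EPCAM (95.8 ± 6.55 to 79.2 ± 3.54 CPM), against 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0289, but adjusted p = 0.607 with an estimated correlation). Without DMSO library 3 or lumacaftor library 1 the hepatocyte and squamous list had camera adjusted p = 0.149 and 0.0624. HEK-293 cells express VIM and KRT18. Of 6 blood cell markers 0 passed the edgeR test or did so adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.837). LCP1 averaged 140 ± 4.24 CPM with DMSO and 125 ± 6.15 CPM with lumacaftor. CD68 stood at 28.3, 28.4 and 142 CPM in DMSO libraries 1, 2 and 3 and at 39.4, 58 and 30 CPM in lumacaftor libraries 1, 2 and 3, and without DMSO library 3 its log2 fold change was 0.58 (adjusted p = 0.044).

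**Figure D3:**
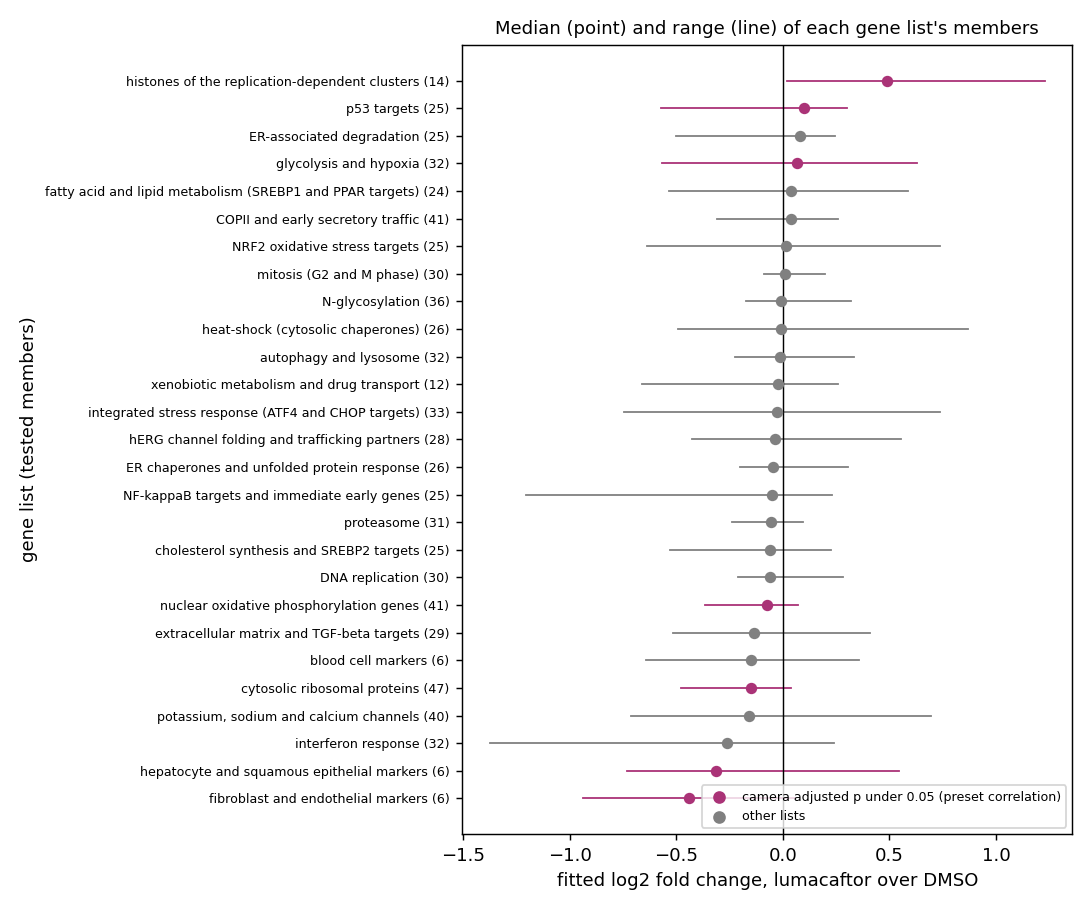
Median (point) and range (line) of the fitted log2 fold changes of the tested members (x axis) of each of the 27 gene lists (y axis), coloured where the camera adjusted p was under 0.05 with the preset correlation. The 7 coloured lists have medians from -0.44 for fibroblast and endothelial markers to 0.49 for histones.

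In the ER chaperone, N-glycosylation and autophagy lists the median fold was negative while the mean and the camera direction were positive. In the fatty acid list the median was positive and the other measures negative, and in the heat-shock list the mean was positive and the other measures negative. None of these 5 lists passed the test.

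The lower genes were richer in GC than the higher genes, with median transcript GC contents of 58.3% and 45.2%, against 50.2% for genes not called. The libraries also differed by GC content. The top decile of GC content minus the bottom decile was 0.12, 0.03 and 0.14 log2 units in DMSO libraries 1, 2 and 3 and -0.23, -0.07 and -0.004 in lumacaftor libraries 1, 2 and 3.

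**Figure D4:**
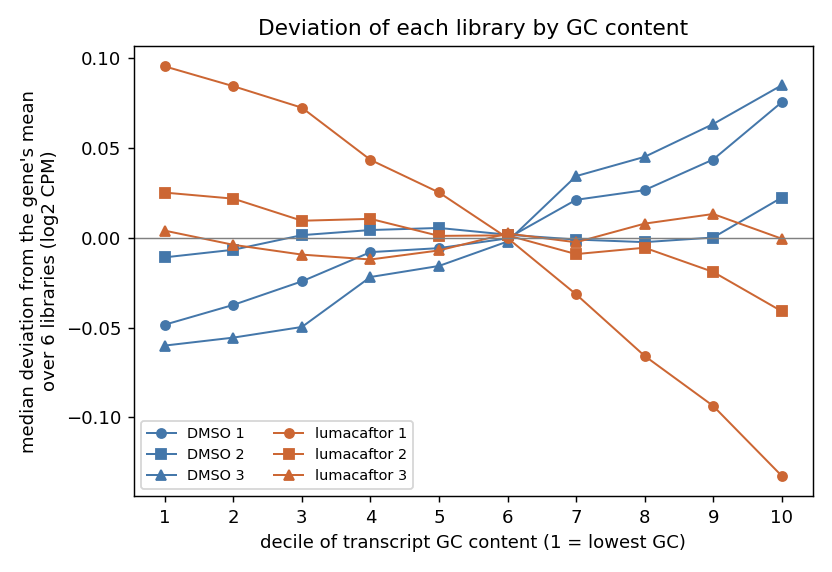
Median deviation of log2 CPM from each gene's mean over the 6 libraries (y axis) for deciles of transcript GC content (x axis, decile 1 lowest), 1 line per library, blue for DMSO and orange for lumacaftor. Lumacaftor library 1 runs from 0.10 in the lowest decile to -0.13 in the highest, and DMSO library 3 from -0.06 to 0.08.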

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

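Of these alternatives, those that used a GC correction, a KCNH2 covariate, a table without KCNH2, or an estimated correlation with a library left out or with the covariate were chosen after seeing the data. RLE, upper-quartile and total-count scaling and limma-voom kept each count of higher and lower genes, with or without the 2-fold limit, within 1.5 times its main value (246 higher and 574 lower, 10 and 30 at 2-fold). DESeq2 gave 19 lower genes at 2-fold, and the stricter filter, which tests fewer genes, 2 higher and 13 lower at 2-fold. An adjusted p of 0.01 left 16 higher and 105 lower (1 and 8 at 2-fold), and glmTreat 4 and 26 (1 and 8 at 2-fold), both by construction. Limma-trend gave 218 lower genes on log2(TPM + 1), with 4 higher and 6 lower at 2-fold, and 215 higher and 213 lower on log2(TPM + 0.1), 14 of the lower at 2-fold. The KCNH2 covariate gave 835 higher and 1241 lower (117 lower at 2-fold), and with the GC correction 790 and 1144 (117 lower at 2-fold); 753 and 628 of the 820 were among them. The causes were not tested. The GC correction by itself called 706 genes, 546 of them shared with the 820.

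With 1 library left out, higher genes ran from 16 to 468, lower genes from 110 to 880, 2-fold higher genes from 2 to 40 and 2-fold lower genes from 9 to 39. The log2 fold change of KCNH2 ran from 0.28 to 1.23 and passed the threshold only without DMSO library 3, and in all other fits that gave it a value it missed. Without DMSO library 3, IFIT1 (0.51), CD68 (0.58) and the interferon list (adjusted p = 1.29e-12) turned from lower to higher and were called; their lowest values over the 6 fits were -0.53 and -1.01, and the highest adjusted p of the list was 0.842. All 63 named changed genes kept their sign in the 6 fits. This was given in advance, since the CPM values of the groups did not overlap for any of them. Of the 63, 10 kept their call in each fit. The calls kept numbered 13 without DMSO library 1, 40 without DMSO library 2, 60 without DMSO library 3, and 14, 12 and 28 without lumacaftor libraries 1, 2 and 3. Across the other fits, 35 and 36 of 63 calls were kept on log2(TPM + 1) and log2(TPM + 0.1) and 55 to 63 with other tools, scalings, covariates or no filter, leaving the block aside; DESeq2 gave no adjusted p for 1 named gene. The stricter filter tested 56 of the 63, and kept each.

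With the replicate number as a block, 52 genes were higher and 227 lower (3 and 14 at 2-fold), 278 of them shared with the 820, and 23 of the 63 named calls were kept. Libraries with the same number did not deviate together (correlations of deviations 0.07, -0.20 and -0.18), and DMSO library 3 correlated best with lumacaftor library 2 (0.31), so the numbers were not read as pairs.

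The number of lists past the threshold was 7 with camera, 0 with an estimated correlation, 0 with directional fry and 23 with mixed fry, which asks another question; with 1 library left out it ran from 6 to 9, and with an estimated correlation it was 0 with any 1 library left out and with the KCNH2 covariate, with or without the GC correction. The ribosomal protein, histone and fibroblast and endothelial lists kept their calls in the 6 fits with 1 library left out; the p53, glycolysis and hypoxia, oxidative phosphorylation and hepatocyte and squamous lists each lost theirs in at least 1, the oxidative phosphorylation list also on both TPM scales and the hepatocyte list with no low-count filter (adjusted p = 0.25). Calls were also gained, in the direction of the full data, by the extracellular matrix list (DESeq2, limma-voom, no filter, log2(TPM + 0.1) and 3 fits with 1 library left out), the proteasome list (DESeq2, limma-voom, the GC correction, without lumacaftor library 1) and the ER-associated degradation list (limma-voom, both TPM scales, without DMSO library 1), and by the COPII and ion channel lists on both TPM scales. With the KCNH2 covariate 5 of the 7 lists lost their call. They were histones (camera adjusted p = 0.175), fibroblast and endothelial markers (0.0706), p53 targets (0.369), glycolysis and hypoxia (0.138) and oxidative phosphorylation (0.116). Another 4 gained one with the preset correlation, and 0 lists passed with an estimated one. The 4 were the interferon list (camera adjusted p = 8.29e-96, 0.318 with an estimated correlation), the integrated stress response (0.00166), NF-kappaB targets and immediate early genes (0.00255) and mitosis (0.00826). With the GC correction as well, 3 were lost and 4 gained. Depth limits genes near 1 CPM, the histone genes among them.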

Other observations

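Of the tests below, the 3 on interferon genes were chosen after their result had been seen, as were the KCNH2 covariate, the GC correction, the share of the most abundant genes and the 3 lists of pathway targets, which were put together because some members had been seen to fall; the tests on the other members were set before those members were looked at.

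Transcripts that ERK signalling is known to induce were lower after lumacaftor. Of 10 tested targets 9 fell. Besides ETV4 and DUSP6, the feedback inhibitor SPRY4 fell from 13.8 ± 1.61 to 6.58 ± 0.991 CPM (SD, n = 3, log2 fold change -1.07 ± 0.14 SE, adjusted p = 0.00402), cyclin D1 (CCND1) from 61.9 ± 1.94 to 41.7 ± 1.07 CPM (adjusted p = 0.00264) and the ephrin receptor EPHA2 from 60.5 ± 1.18 to 42.1 ± 2.06 CPM (adjusted p = 0.00314). Among the 5 members not looked at before, DUSP4, ETV5, SPRY2 and PHLDA1 fell, with log2 fold changes of -0.75, -0.76, -0.46 and -0.42, and EPHA4 had -0.27 (adjusted p = 0.09).

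Some targets of retinoic acid and of Wnt signalling were also lower. Of 12 tested retinoic acid targets 5 fell, the retinol pathway genes STRA6 (47.8 ± 3.49 to 31.8 ± 2.17 CPM), DHRS3 and CRABP2 and the homeobox genes HOXB2 and HOXA2, with log2 fold changes from -0.55 to -0.61. For the 9 members not looked at before, the hypothesis of lower retinoic acid signalling may be kept, since the rotation test fry gave p = 0.00125 (down), with a median of -0.53 and an exact permutation p of 0.1 over the 6 libraries, though 2 of the 9 passed the threshold, with all 9 folds negative. Of 12 tested Wnt targets 3 fell, APCDD1 (-0.68), TBXT (-0.92) and NOTUM (-0.60), while AXIN2 (-0.12, adjusted p = 0.458) and LEF1 (-0.19, adjusted p = 0.125) missed the threshold. For the 10 Wnt members not looked at before, fry gave p = 0.016 (down), with a median of -0.15 and an exact permutation p of 0.1, but 1 of the 10 passed the threshold (NOTUM), 7 had negative folds, and NKD1, TNFRSF19 and ZNRF3 had positive ones (0.03, 0.08 and 0.15). After the GC correction 2 Wnt targets stayed lower, NOTUM moving from -0.60 ± 0.14 to -0.46 ± 0.14 (SE, adjusted p = 0.0798), and with the KCNH2 covariate 4 were lower and 1, ZNRF3, higher (0.26 ± 0.08 SE). Lower Wnt signalling may be kept as a hypothesis for some of these genes, not for the targets as a whole. The exact p of 0.1 is the smallest that 3 against 3 libraries allow. Adjusted over the 3 added lists, fry gave adjusted p = 0.000754 for ERK, 0.00188 for retinoic acid and 0.016 for Wnt targets. Fry does not compare a list with other genes, and pathway activity was not measured.

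The ERK targets were weighed against technical explanations. GC content bias between libraries is argued against as the whole cause, since 9 of the 10 targets were lower past the threshold after the GC correction. With the KCNH2 covariate 9 of the 10 were also lower. That fit cannot exclude the amount of transfected plasmid transcript, because the KCNH2 levels of the groups overlap through DMSO library 3 only. Both counts include the 5 members that had been seen to fall before the list was made. The hypothesis of lower ERK signalling after lumacaftor was tested on the 5 members not looked at before, which were lower (fry p = 0.000251, exact permutation p = 0.1). It may account for these genes, but it rests on transcripts of the same libraries, and 3 per group cannot exclude a culture difference that follows treatment.

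Interferon genes differed between libraries of a group and were highest where KCNH2 was highest in that group. The amount of transfected plasmid transcript is thus a candidate explanation. The order of the libraries matched only in part. Lumacaftor library 3 had more KCNH2 than lumacaftor library 1 (11265 against 10881 CPM) but a lower median of the interferon list (6.99 against 7.27 log2 CPM). Lumacaftor library 2 had the most KCNH2 (16817 CPM) but lay below DMSO library 3 (7.55 against 8.14). In both groups all 32 tested members were highest in the library with the most KCNH2, where chance gives 3.56 if genes are independent, which co-regulated genes are not. With log2 KCNH2 as a covariate 32 of 32 rose with KCNH2 (median 0.98 log2 per doubling), and 22 did without DMSO library 3. Library depth is argued against, since the median fold between DMSO libraries 3 and 2 was 3.02 while their totals were 16222888 and 16016452. With the covariate 31 of 32 were lower after lumacaftor, with a median log2 fold change of -0.75 (median SE 0.08). Without DMSO library 3 the median was -0.76 with 31 of 32 negative, but its median SE was 0.21 and 7 passed, in a fit that called 26 genes in all, since the KCNH2 levels of the groups then no longer overlap. In the other fits with 1 library left out, 28 to 31 passed. Whether lumacaftor lowers interferon genes at a given KCNH2 level cannot be told apart from an effect of KCNH2 itself, because KCNH2 may respond to treatment and its levels overlap through DMSO library 3 only.

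Lower genes outnumbered higher genes (70% of calls) and were richer in GC. A few genes taking most of the counts is argued against by the 20 genes with the most counts, which held 5.83% to 6.82% of each library, so that on library totals they shift all other genes by -0.0052 log2 between the groups (-0.015 to 0.006 over the 9 pairs of a lumacaftor and a DMSO library), against a median of -0.41 for the lower genes. Gene length bias is argued against as the whole cause of the excess by the 75% of calls that were lower among the 6931 genes of middle length. The lower genes were also shorter, with a median transcript length of 1770.5 nucleotides against 2793 for the higher genes. A part played by length, which that subset does not separate from GC content, stays open. GC content bias between libraries stays open as a candidate explanation, since after the GC correction 64% of calls were lower. That share lies between the limits of 55% and 65%, in a test chosen after the data had been seen. The trend with GC follows the groups, so an effect of lumacaftor on GC-rich genes is open too, untested. After that correction the median GC content was 51.4% for lower and 56.2% for higher genes, and on log2(TPM + 1) and log2(TPM + 0.1) 50.7% and 49.8% of calls were lower. The TPM fits had no TMM scaling and a median log2 fold change over all tested genes of 0.06 and 0.07, so scaling may have part in those shares.

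The 6 libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real division called 820 genes, and 40 at 2-fold, and the highest other division called 0 of either with edgeR (1 of 10 divisions as large for each); the other divisions had 129 to 896 genes at an unadjusted p under 0.05, with up to 27 called by DESeq2 and up to 1 by limma-voom. For gene lists past the camera threshold, the real division gave 7 and the highest other 10, and 4 of the 10 gave as many.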
